A study of Homo sapiens with 6 samples.

How the data were processed

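The series measured gene expression by RNA sequencing in 6 libraries of human cells. Per the labels' protocols, total RNA was extracted with TRIzol, messenger RNA was captured on poly-T beads, first-strand cDNA was primed with random hexamers and the libraries were amplified by PCR. Of the libraries, 3 came from the hTERT A41hWAT-SVF line (called WT here) and 3 from an APP-knockout line made from it (called APP_KO). Each library was placed in its group by its title, which also gives its replicate number. The design text calls the replicates biological; a date or batch of culture, editing or sequencing is not given in the sources used here. Whether the APP_KO libraries come from 1 edited clone, a pool or several clones is not given in the sources used here, so the p-values measure the spread between these libraries and are not known to cover that between independently edited lines.

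The authors deposited, for each gene and library, a normalised signal: the gene's read count divided by a size factor of the library. Per the submitters' processing notes, the tools were fastp, HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and DESeq2 1.20.0, with genome build hg38; their roles, options and strand setting and the annotation release are not given in the sources used here. In the deposited signal every value was a whole multiple of the library's smallest value above 0, within a tolerance of 0.001 of a read, for 100% of values in each library. The whole reads were therefore recovered, and the ratio of the deposited size factors to those DESeq2 1.42.0 computes from these reads was 1 in every library. The authors' deposited table also holds a log2 fold change, a p-value and an adjusted p-value per gene for APP_KO against WT, with gene positions and biotypes. The adjusted p-value is exactly 1 for 5768 genes in the authors' deposited table. A second deposited table by the authors gives, for KEGG pathways, the number of their changed genes in each and a p-value. A further 2 columns of values, named for a group and not for a sample, were not used here.

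Recovered reads on genes numbered 16977890, 18750996 and 16978903 in WT replicates 1 to 3 and 16834129, 15266570 and 16524322 in APP_KO replicates 1 to 3. A count of 0 in a library allows a normalised value of up to 2.58 to 3.41, which is 3 reads divided by the size factor. Such floors and the 95% binomial intervals (exact Clopper-Pearson) cover counting error only, since the reads carry no molecular identifiers. Pairs of replicates of a group differed by more than counting noise, with a chi-square per degree of freedom from 2.04 to 3.37, which separate library preparation can also give. Each library was counted as a replicate because the design text calls the replicates biological.

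Because the deposited values are a signal and not raw counts, the main test was limma 3.58.1 (R 4.3.3) on log2(value + 0.5), with an intensity trend and robust variance, two-sided. The design fixed before the data were examined had assumed raw counts and edgeR's quasi-likelihood test; that test was run on the recovered reads as an alternative chosen after seeing the data and called 9680 genes. Of the 27051 genes in the table, 14906 were tested after edgeR's (4.0.16) filterByExpr with a minimum count of 10 and a minimum total of 15. The 12145 genes left out held 0.159% of the reads. Benjamini-Hochberg adjustment covered all tested genes, with a threshold of 0.05. Fold changes are on the log2(value + 0.5) scale and understate changes of low genes. Where a group has no read of a gene, the fold is a lower bound computed against 3 reads per library; with 1 to 3 reads it is the ratio of the groups with its 95% counting interval.

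Also beforehand, 40 gene lists with 865 entries (824 different genes) were fixed from textbook knowledge, 7 of them markers of other cell types. By symbol, 808 entries were found, 3 through a table of older symbols, and 54 were not analysed here. The 35 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, two-sided, with adjustment over lists. The design had assumed log2 CPM with a prior count of 2. The test used the same log2 values as the gene test instead, and an offset of 2 in place of 0.5 was an alternative. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other tested genes; fry asks whether a list's genes move, on balance, one way. Genes were named by a rule fixed at the same time. It takes APP, APOE and 6 adipocyte genes, the 10 largest rises and 10 largest falls among protein-coding genes with mean log2 CPM of at least 1 and groups that do not overlap, up to 4 changed members of each list, and up to 4 changed genes of highest expression in a chromosome or window. The last part was applied to chromosomes whose median differed from the others by at least 0.25 and to the highest and the lowest window. Genes outside the rule are said to be so where they are named.

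For each chromosome with at least 100 tested genes, the median log2 fold change was compared with that of all tested genes by 10000 permutations of the genes, and likewise for windows of 50 neighbouring tested genes. Neighbouring shifted windows of the same direction were joined into segments. Positions are those of the authors' deposited table, in hg38. On simulated data with the real means and depths, limma recovered 46%, 62%, 90% and 98% of genes changed 1.25-fold, 1.5-fold, 2-fold and 4-fold among 14906 genes and called 4 of 14706 unchanged genes. Camera called the changed list and 0 of 20 unchanged lists. On shuffled positions 2 of 460 chromosomes were called, and a raised chromosome was called. The simulation drew genes independently and changed 50 genes at each fold, far fewer than changed in the real data. Shuffling likewise separates neighbouring genes. The list and chromosome checks therefore do not cover correlated genes, and the estimated correlation reached 0.527 in the collagen list.

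Alternatives fixed beforehand were other scalings (upper quartile factors, library size only), no filter and a stricter one (CPM above 1 in 3 libraries), pseudocounts of 0.1 and 1, variance without robust estimation, DESeq2 and limma voom on the recovered reads, the replicate number as a block, a threshold of 0.01, windows of 100 genes, protein-coding genes only, camera with an estimated correlation, fry, and leaving out each library. Chosen after seeing the data were TMM scaling, the edgeR test, centring each window of genes on its median, and list tests without genes of shifted windows or, for the list of its family, without APP. FABP4, ADIPOQ and LPL were not analysed here. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.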

Results

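RNA sequencing compared hTERT A41hWAT-SVF cells, a human line of white adipose tissue progenitors from the stromal-vascular fraction immortalised with telomerase, with APP-knockout cells made from it by CRISPR-Cas9. The design text also calls the knockout conditional; how that applies to these libraries, and whether the edited cells are clonal, is not given in the sources used here. APP encodes the amyloid precursor protein, a membrane protein known for its part in Alzheimer's disease, and the knockout was made to ask what APP does in adipogenesis. There were 3 WT and 3 APP_KO libraries. The growth protocol describes maintenance medium, and a differentiation step for these libraries is not given in the sources used here. Reads on genes ranged from 15266570 to 18750996 per library, and 21957 to 22707 genes had at least 1 read in a library. Across tested genes, log2 values correlated at 0.989 to 0.991 between libraries of a group and at 0.922 to 0.926 between groups, and the first principal component held 83.8% of the variance. The 10 most abundant genes took 7.64% to 7.82% of reads in WT and 11.1% to 11.2% in APP_KO libraries. In what follows, levels are normalised read counts (mean ± SD, n = 3 libraries per group), numbers after a gene are log2 fold changes of APP_KO over WT, and adjusted p-values are from limma with Benjamini-Hochberg adjustment over 14906 genes. Genes are said to rise or fall only where they passed the threshold of 0.05.

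APP itself, the targeted gene, fell from 12308.9 ± 57.4 in WT to 99.3 ± 3.64 in APP_KO (log2 fold change -6.95, SE 0.052, adjusted p = 5.36e-32), a 123.4-fold lower level. Each APP_KO library was far under each WT library: the values were 12285.4, 12267 and 12374.3 in WT and 103.379, 96.4985 and 97.9061 in APP_KO. The gene (ENSG00000142192) lies on the minus strand of chromosome 21 from 25880550 to 26171128 in hg38, a span of 290579 bases with 17 transcripts in GENCODE v29. The guide's target site, and with it the exon or intron edited, is not given in the sources used here, and read counts of whole genes do not show it. Among neighbours, chosen by position, the nearest tested genes below APP in position, ATP5PF (-0.14, adjusted p = 0.0741) and GABPA (0.087, adjusted p = 0.274), did not pass the threshold. On the other side the extracellular proteases ADAMTS1 (-1.13) and ADAMTS5 (-0.34) both fell.

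Among the 23 tested genes of APP's family and processing, 9 rose and 10 fell. APP's homologues moved apart: APLP1 fell from 546.7 ± 45.1 to 132.5 ± 23.1 (-2.05, SE 0.11), while APLP2 rose from 19193.9 ± 635.3 to 39958.9 ± 3278 (1.06, SE 0.046). SORL1, a sorting receptor that binds APP, fell (-1.99, SE 0.26). As a list these genes did not pass camera's threshold (adjusted p = 0.732, median -0.071), while fry called them downward (adjusted p = 4.12e-05). That call rested on APP itself, a member of the list: without APP, fry's adjusted p was 0.344 and camera's 0.954 with the direction upward, at a median of -0.060.

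Among the gene lists, those of collagens and matrix glycoproteins rose in APP_KO and those of cholesterol synthesis, fatty acid and triglyceride synthesis and DNA replication fell. These are calls of camera at its preset correlation, and with an estimated correlation their adjusted p ranged from 0.273 to 0.425. CDH6, a cadherin, had no read in any WT library and reached 4263.64 ± 279.3 in APP_KO, at least 1542-fold higher. COL1A2 rose from 43698.2 ± 1424 to 268234 ± 9979, PPARG, the master regulator of adipogenesis, fell from 914.3 ± 15.3 to 288.3 ± 8.08, and the tetraspanin CD9 fell from 2863.7 ± 54.3 to 189.5 ± 21.4. Of the 14906 genes tested, 9612 changed, 4564 higher and 5048 lower, which is 64.5%. At least 2-fold changes were fewer, with 1201 genes higher and 1019 lower, and 4-fold changes fewer still, 323 and 342. The median size of a called change was 0.53 on the log2 scale. In 10092 genes (67.7%) every library of a group lay above every library of the other group, against 10% by chance, and 9212 of the changed genes were among these. Of the genes named here as changed, only MT-ATP8 and BNC1 had overlapping groups. With scaling by library size only, 3632 genes were higher and 6094 lower (37.3% higher, against 47.5%), and the median of all genes moved to -0.11.

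**Figure D1:**
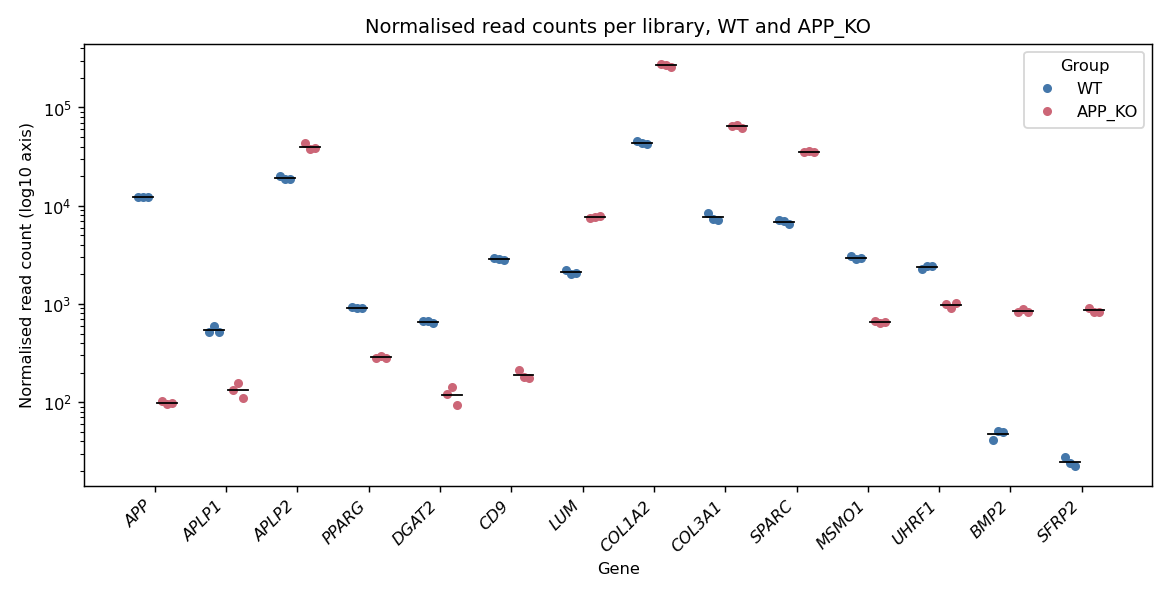
Normalised read counts (log10 axis) of 14 genes named in the text, with a point per library (WT blue, APP_KO red) and a bar at the mean of 3 libraries. In each gene the groups do not overlap, from APP (12308.9 in WT, 99.3 in APP_KO) to SFRP2 (24.9 and 864.0).

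Among the 10 largest rises, which included that of CDH6, the cadherin CDH13 went from 2 reads over the WT libraries to 1699.7 ± 100.9, a ratio of 2774 with a counting interval of 767.4 to 22910. The contactin CNTN3 was at least 169.7-fold higher and CNTNAP5 at least 40.84-fold higher, both without a WT read. BCHE (butyrylcholinesterase, at least 152.6-fold) and MOB3B (at least 38.43-fold) were also without WT reads. ADRA2A, an alpha-2 adrenergic receptor, had 2 WT reads (ratio 473.4, interval 130.6 to 3916) and ADGRE1, an adhesion G-protein-coupled receptor, had 1 (ratio 791.8, interval 141.6 to 31320). MKX, a transcription factor of tendon, rose by 8.09 (SE 0.53) and the transporter gene SLC7A14 by 7.51 (SE 0.72). The 10 largest falls included APP and genes without a read in APP_KO: PPFIBP2 (at least 44.22-fold lower), the laminin LAMA1 (at least 33.44-fold), the GTPase RHOD (at least 28.36-fold) and HENMT1 (at least 19.41-fold). ZNF536 had 1 APP_KO read (ratio of WT to APP_KO 458.8, interval 81.99 to 18150). TMEM98 (-8.05), GALNT6 (-7.83), TMEM246 (-7.34) and the protocadherin PCDH10 (-7.07) completed the falls.

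The tested adipocyte genes were mostly lower in the knockout line, though as a list they missed the threshold. This list holds 25 genes, of which 18 were found and 10 passed the low-count filter, so much of the program is not covered. Of the 10 tested members of the adipocyte program, 7 fell and 1 rose (median -1.23): DGAT2, which makes triglyceride, fell (-2.49, SE 0.12), as did the lipid-droplet gene PLIN4 (-1.72) and PPARG (-1.66, SE 0.069), and the fatty-acid transporter CD36 rose (1.04). CIDEA, a lipid-droplet gene outside the naming rule and chosen after its values were seen, had no APP_KO read and was at least 6.42-fold lower. Camera's adjusted p was 0.0652; it was 0.0362 without APP_KO replicate 2, and 0.009 to 0.217 over the alternatives at the preset correlation. CEBPA (5.61 ± 3.50 in WT, 2.15 ± 1.05 in APP_KO) and PLIN1 (0.607 ± 0.528 and 0) lay below the filter and were not tested. The early regulators of adipogenesis went both ways (11 of 20 rose and 7 fell, camera adjusted p = 0.164; 12 and 7 adjusted over the list alone). BMP2 rose from 47.6 ± 5.51 to 848.8 ± 39.1 (4.15), KLF4 rose (0.95), and FGF1 (-1.59) and NR1H3, the oxysterol receptor LXR alpha (-1.11), fell. Inhibitors of adipogenesis numbered 10 rises and 4 falls among 16 (camera adjusted p = 0.0703), with GATA2 (1.87) and TWIST1 (1.15) higher and SFRP1 (-1.38) and KLF2 (-1.03) lower.

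Adipose progenitor markers rose as a list, with 14 of 20 higher and 5 lower (median 0.60, camera adjusted p = 0.00805; adjusted p = 0.548 with an estimated correlation; 14 and 6 adjusted over the list alone). The tissue factor gene F3 (2.18), WISP2 (1.93) and the proteoglycan LUM (1.87, from 2107.1 ± 104.2 to 7684.2 ± 197.2) rose, whereas CD9 fell most (-3.92, SE 0.070). Thermogenic genes showed 2 rises and 6 falls among 9 (camera adjusted p = 0.279; 3 and 6 adjusted over the list alone). TMEM26 rose (3.91), and UCP2 (-1.62), the creatine kinase CKB (-1.12) and PRDM16, a regulator of brown fat identity (-0.89), fell. Bone and cartilage genes were split, 4 higher and 4 lower among 9 (camera adjusted p = 0.43): BMP2, SOX9 (0.74) and RUNX2 (0.72) rose, and the osteopontin gene SPP1 fell (-2.03).

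Extracellular matrix genes rose together. Of 18 tested collagens of fibrils and basement membranes, 15 rose and 2 fell (median 1.55, camera adjusted p = 5.61e-09; adjusted p = 0.425 with an estimated correlation). COL15A1 rose most (6.09, SE 0.13), followed by COL3A1 (3.07, SE 0.047; 7650.3 ± 649.0 to 64062.1 ± 2107) and COL1A2 (2.62, SE 0.031), and COL14A1 fell (-3.13, SE 0.15). COL1A1 and COL1A2 together took 0.507% to 0.547% of reads in WT libraries and 2.68% to 2.81% in APP_KO libraries. Glycoproteins and proteoglycans of the matrix followed, with 19 of 26 higher and 4 lower (median 0.84, camera adjusted p = 1.26e-07; adjusted p = 0.33 with an estimated correlation). Periostin POSTN (2.46), SPARC (2.37), tenascin TNC (2.09) and LUM (1.87) led them. Matrix-remodelling enzymes went both ways, 13 higher and 10 lower of 24 (camera adjusted p = 0.212). ADAMTS12 (1.99), MMP3 (1.84) and MMP12 (1.61) rose, and the protease inhibitor TIMP4 fell (-2.80).

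Integrin and focal-adhesion genes were likewise divided (12 higher and 9 lower of 24, camera adjusted p = 0.522; the median of 0.092 turned to -0.013 with library size only). ITGB8 rose from 107.0 ± 16.6 to 3099.1 ± 64.4 (4.86), and ITGA6 (-3.16), ITGA7 (-2.10) and ITGB3 (-1.71) fell. Targets and members of the TGF-beta and YAP pathways had 10 rises and 8 falls among 19 (camera adjusted p = 0.327). PMEPA1 (3.23), TGFBI (2.34), TGFB2 (1.85) and CTGF (1.60) rose. Contractile genes showed 5 rises and 5 falls among 14 (camera adjusted p = 0.793; 5 and 6 adjusted over the list alone). The calponin CNN1 (-3.77) and SYNPO2 (-1.09) fell, and smooth-muscle actin ACTA2 (1.37) and the myosin kinase MYLK (0.91) rose.

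Cholesterol synthesis genes fell in the knockout line. Of 25 genes 21 fell and 2 rose (median -0.81, camera adjusted p = 1.03e-07; adjusted p = 0.425 with an estimated correlation). The sterol enzymes MSMO1 (-2.17, SE 0.049), TM7SF2 (-1.64) and NSDHL (-1.55) fell. Fatty acid and triglyceride synthesis fell too, 15 of 21 genes lower and 2 higher (median -0.32, camera adjusted p = 0.000224; adjusted p = 0.425 with an estimated correlation). Beside DGAT2, the phosphatidate phosphatase LPIN1 (-1.17) and the desaturases SCD (-1.12, 17141.8 ± 485.9 to 7915.5 ± 731.9) and FADS2 (-1.03) fell. Lipolysis and fatty acid oxidation had 8 genes higher and 8 lower of 21 (camera adjusted p = 0.906, fry downward with an adjusted p of 0.00293; a median of 0.0017, which was -0.012 with TMM and -0.10 with library size only). PDK4 rose (0.84), and hormone-sensitive lipase LIPE (-0.79), HADH (-0.79) and the carnitine transferase CPT1A (-0.71) fell.

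APOE, named in the title of the study as a signalling partner of APP, was scarce in this line and fell from 15.9 ± 1.13 to 1.83 ± 1.72 (-3.25, SE 0.72, adjusted p = 3.62e-04). In its list of APOE and lipoprotein receptors 2 of 15 genes rose and 8 fell (median -0.16, camera adjusted p = 0.0932; 2 and 9 adjusted over the list alone). Clusterin CLU (-1.69) and SCARB1 (-1.03) fell, and the cholesterol exporter ABCA1 rose (1.39).

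DNA replication genes fell almost as a whole: 28 of 30 were lower and 0 higher (median -0.59, camera adjusted p = 5.61e-09; adjusted p = 0.273 with an estimated correlation). GINS2 (-1.33), UHRF1 (-1.29, 2377.9 ± 86.6 to 976.3 ± 64.3), GINS3 (-1.18) and MCM10 (-1.16) had the largest falls. Of 30 mitotic genes 14 were lower and 6 higher (median -0.18, camera adjusted p = 0.135). Over the alternatives at the preset correlation that adjusted p ranged from 0.00642 with window-centring to 0.211, and the list was also called without the low-count filter (0.0237). Among its members CCNA2 (-0.97), BUB1 (-0.89), BIRC5 (-0.78) and CENPE (-0.76) fell. Targets of p53 and senescence genes numbered 12 rises and 7 falls of 24 (camera adjusted p = 0.286; a median of 0.091, and -0.014 with library size only). FDXR (1.32), ZMAT3 (1.14), BBC3 (1.10) and CCNG1 (0.80) rose.

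Interferon-response genes rose, 16 of 24 higher and 0 lower (median 0.53, camera adjusted p = 0.00134; adjusted p = 0.273 with an estimated correlation). IFI44L (1.94), IFI27 (1.63), XAF1 (1.49) and IFIT1 (1.49) had the largest rises under the naming rule, and CMPK2, outside it and chosen after its values were seen, had no WT read and was at least 7.33-fold higher. Antigen-presentation genes rose with them, 12 of 18 higher and 2 lower (median 0.44, mean 0.097, camera adjusted p = 0.0139; adjusted p = 0.425 with an estimated correlation). Without APP_KO replicate 1 this camera call was lost (adjusted p = 0.0503), with a range of 0.00957 to 0.0503 over the alternatives at the preset correlation. HLA-B (0.95) and the peptidases ERAP1 (0.92) and ERAP2 (0.90) rose, and the class II gene HLA-DPA1 fell from 73.0 ± 5.47 to 1.42 ± 1.59 (-5.67). HLA genes resemble each other, and reads shared between them were not separated. Cytokines and NF-kappaB genes had 9 rises and 5 falls among 19 (camera adjusted p = 0.279; 10 and 5 adjusted over the list alone), with CXCL8 (2.14), CXCL1 (2.13), CCL2 (1.95) and LIF (1.55) higher.

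Genes of signalling pathways changed in both directions. Of 25 Wnt genes 12 rose and 9 fell (camera adjusted p = 0.435; 12 and 10 adjusted over the list alone). The secreted Wnt antagonists SFRP2 (5.10, from 24.9 ± 2.70 to 864.0 ± 45.7) and SFRP4 (4.65) rose and the receptors FZD8 (-2.53) and FZD4 (-1.41) fell. Of 8 Notch genes 5 rose and 1 fell (camera adjusted p = 0.289), JAG1 (1.85), NOTCH1 (0.35) and MAML2 (0.34) higher and RBPJ (-0.89) lower. Insulin and IGF genes had 7 rises and 8 falls of 18, with a median of -0.065, a mean of 0.81 and an upward camera direction (adjusted p = 0.486). The binding proteins IGFBP3 (6.91), IGFBP5 (5.81) and IGFBP7 (2.19) and the kinase subunit PIK3R1 (1.22) rose. Immediate early genes had 10 rises and 9 falls of 21, with a median of 0.21, a mean of 0.26 and a downward camera direction (adjusted p = 0.889). EGR1 (2.48) and EGR3 (2.41) rose, and SPRY2 (-1.44) and FOSL1 (-1.40) fell.

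Cytosolic ribosomal protein genes rose slightly, 30 of 40 higher and 5 lower (median 0.19, camera adjusted p = 8.7e-05; adjusted p = 0.636 with an estimated correlation); with library size only the median was 0.081. They were led by RPL37 (1.23), RPS25 (0.73), RPL11 (0.68) and RPL5 (0.67). Reads shared with their many processed pseudogenes were not separated. Camera called 0 of the 5 stress and energy lists that follow, and at an unadjusted p under 0.05 also 0, whereas fry called the first 2. The unfolded protein response had 5 rises and 10 falls of 22 (camera adjusted p = 0.412, fry downward with 0.0094); CHAC1 (-1.87), TRIB3 (-1.74), ASNS (-1.24) and PPP1R15A (-1.11) fell. Hypoxia and glycolysis genes had 7 rises and 14 falls of 28 (camera adjusted p = 0.289, fry downward with 0.03; 8 and 14 adjusted over the list alone), with CA9 (-2.87), SLC2A3 (-0.87), PFKFB4 (-0.84) and VEGFA (-0.58) lower. Nuclear genes of oxidative phosphorylation had 11 rises and 11 falls of 33 (camera adjusted p = 0.889, median -0.056, mean 0.026, direction upward; 11 and 12 adjusted over the list alone). SDHA (1.3) and SDHD (0.58) rose, and NDUFS1 (-0.58) and NDUFB3 (-0.58) fell. Mitochondrially encoded genes had 3 rises and 5 falls of 13 (camera adjusted p = 0.655), from -0.39 for MT-ATP8 and -0.22 for MT-CO2 to 0.11 for MT-CO1 and 0.19 for MT-CYB. NRF2 targets and metallothioneins had 6 rises and 7 falls of 17 (camera adjusted p = 0.906). AKR1C1 (1.76) and AKR1C3 (1.27), paralogues that may share some reads, rose, and the cystine transporter SLC7A11 (-1.39) and OSGIN1 (-1.04) fell.

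Markers of other cell types were low or mixed. Neural and glial markers had 5 rises and 2 falls among 9 (median 1.05, camera adjusted p = 0.0733; adjusted p = 0.425 with an estimated correlation), and over the other alternatives camera's adjusted p ranged from 0.0322 with library size only to 0.102. Among them were MAP2 (2.31), NEFL (2.06), SYT1 (1.41) and NEFM (1.05, from 1550.2 ± 100.6 to 3214.4 ± 103.0), all higher. Pericyte and smooth-muscle markers had 1 rise and 3 falls among 6 (camera adjusted p = 0.605): CSPG4 (-1.17), MCAM (-0.81) and KCNJ8 (-0.54) fell and ABCC9 (0.72) rose. The other marker lists had fewer than 5 tested members. Endothelial markers had 1 rise, PECAM1 (0.82), and 1 fall among 4. The only tested member of the list of macrophage and leukocyte markers, CSF1R (0.98, from 41.4 ± 10.7 to 82.1 ± 18.7), rose. ADGRE1, named above among the largest rises, is not in that list. Epithelial markers had 2 rises, the larger in KRT19 (3.24), and 1 fall among 4 (2 and 2 adjusted over the list alone). Mesothelial markers had 2 rises among 3, KRT19 again and BNC1 (0.68, adjusted p = 0.0252), whose call was lost without WT replicate 2 (adjusted p = 0.113) or 3 (0.0788) and without APP_KO replicate 2 (0.162) or 3 (0.0531), with a range of 0.00717 to 0.162 over all alternatives. Skeletal muscle markers had 1 rise, MYH3 (1.09), and 2 falls, TNNT1 (-1.24) and PAX3 (-0.58), among 3.

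Over all fixed lists, camera called 9 of 35, 6 upward and 3 downward, and 13 had an unadjusted p under 0.05. With an estimated correlation 0 lists were called, and 3 had an unadjusted p under 0.05; with fry 31 were called, 18 upward and 13 downward, among them the 9 and, resting on APP, the list of its family. Camera called 0 of the 2 tested marker lists (1 at an unadjusted p under 0.05), and fry called 2. Where no count adjusted over the list alone is given, it was that over all genes. Without the genes of the shifted windows described next, the camera adjusted p of the 9 called lists ranged from 2.59e-07 (DNA replication) to 0.0268 (antigen presentation), and early adipogenic regulators (0.0212), bone and cartilage genes (0.0212) and mitotic genes (0.0311) were called as well. Under TMM, upper quartile factors and library size only, 0 list members had a call that changed direction.

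**Figure D2:**
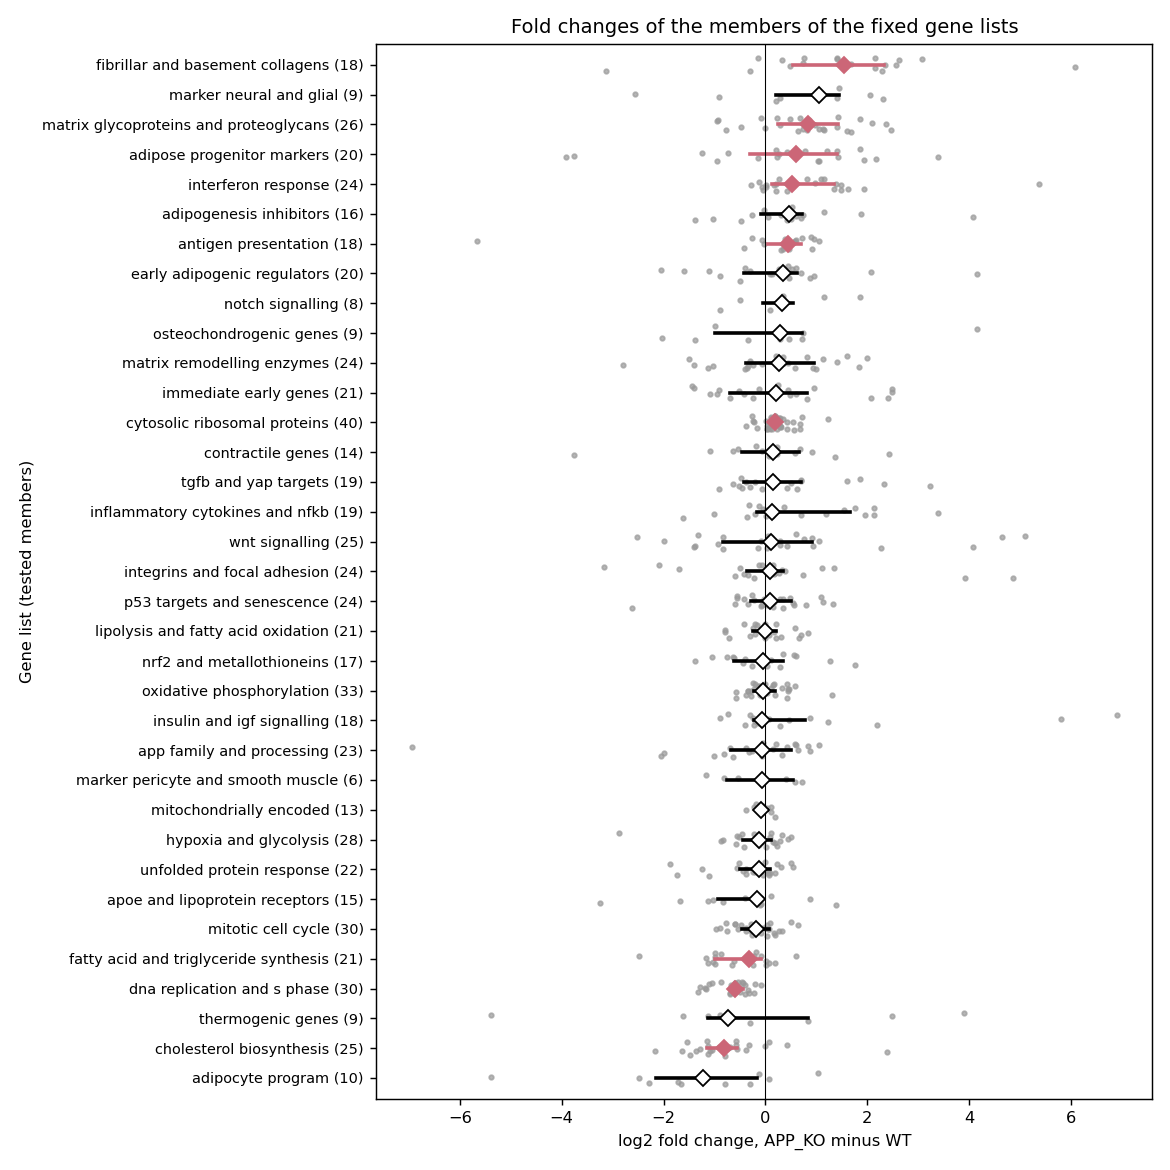
Log2 fold changes (APP_KO minus WT) of tested members of the 35 fixed gene lists with at least 5 tested members, each grey point a gene, each diamond the median and each bar the interquartile range. Red marks the 9 lists that camera called at a preset correlation of 0.01, from the collagens (median 1.55) to cholesterol biosynthesis (median -0.81).

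Expression also shifted by chromosomal region. Genes of chromosome 5 were higher in the knockout line (median 0.40, 414 higher and 102 lower of 700), as were those of chromosomes 20 (0.25) and 22 (0.25), and genes of chromosomes 4 (-0.38, 306 lower and 70 higher of 518) and X (-0.34) were lower. On chromosome 5 the matrix genes VCAN (1.60), TGFBI (2.34) and SPARC (2.37) and the ribosomal RACK1 (0.51) rose. On chromosome 4 the annexin ANXA5 (-0.99), RBPJ (-0.89) and WDR1 (-0.12) fell, and PDGFRA (0.23) rose. GNAS (0.37), RRBP1 (0.56) and CTSA (0.35) rose and YWHAB (-0.19) fell on chromosome 20, and MYH9 (0.96), FBLN1 (1.14), DDX17 (0.58) and RPL3 (0.18) rose on chromosome 22. On the X chromosome the filamin FLNA rose (0.18), and RPL10 (-0.22) and MSN (-0.34) fell. In total 13 of 23 chromosomes passed the permutation test: 1, 2, 4, 5, 9, 11, 12, 17, 18, 19, 20, 22 and X. For 10 of them p was 1e-04, the smallest that 10000 permutations can give (adjusted p = 0.00023). The permutation treats genes as independent, which neighbouring genes are not.

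Within chromosomes the shifts covered long stretches. Of 287 windows, 90 were shifted, 52 higher and 38 lower, and they held 4643 (31.2%) of the 14861 tested genes placed in windows. Joined, they formed 33 segments, 14 higher and 19 lower. The 3 largest upward segments by number of genes ran on chromosome 1 from 14404 to 77559969 (650 genes, median 0.34), on chromosome 5 from 72095855 to 181324685 (500 genes, 0.34) and on chromosome 20 from 19757606 to 64287821 (288 genes, 0.35). Downward, chromosome 2 from 112370092 to 242160153 (476 genes, -0.36) and chromosome 4 from 70815782 to 190015255 (318 genes, -0.55) were the largest. The X chromosome changed direction along its length, -0.45 from 15790472 to 102885406, 0.66 from 102884414 to 133415490 and -0.54 from 133535745 to 156025710. The highest window, on chromosome 5 from 92151 to 14871785, lay 1.06 above the median of all genes and held AHRR (1.73), TRIO (1.36), CCT5 (0.66) and TERT (0.48, from 10344.9 ± 532.2 to 14457.3 ± 522.3); the line carries a telomerase transgene, so reads of TERT need not come from this position. The lowest, on chromosome 4 from 121035613 to 143223830, lay -0.70 from it and held TBC1D9 (-1.24), ANXA5, SETD7 (-0.89) and KIAA1109 (-0.49). The segments and chromosomes were picked for a shift between these same libraries, so values by library show its spread and are no separate evidence. Every APP_KO library lay outside the WT range in all 33 segments and in 12 of the 13 chromosomes, chromosome 19 being the exception. Of the 73 named genes in shifted windows, 61 lay on the side of their window and 12 on the other. Among the former were MSMO1, NSDHL, CCNA2, RPL37, RPL11, ERAP1, ERAP2 and SDHA, and among the latter COL3A1, SFRP2, IGFBP3, IGFBP5, CXCL8 and MAP2. Over all tested genes of the segments, 76.5% lay on their segment's side. Some named genes were also picked for lying in the highest or lowest window, so this count says little about the named genes.

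**Figure D3:**
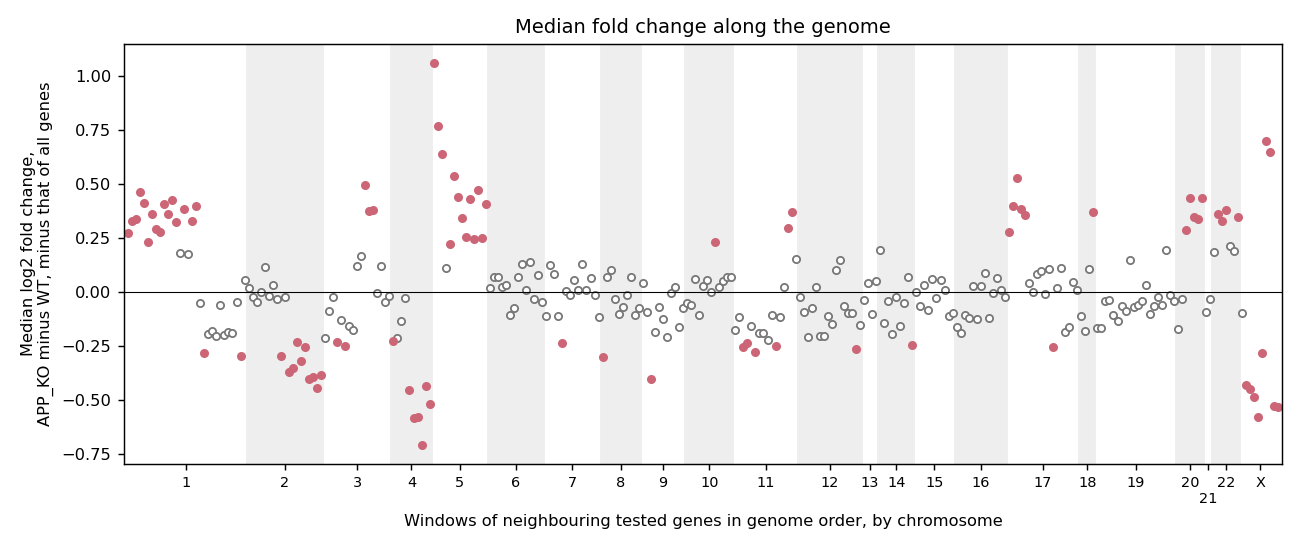
Median log2 fold change (APP_KO minus WT) of windows of 50 neighbouring tested genes, minus the median of all genes, in genome order with chromosomes separated by shading. Filled red points are the 90 windows past the permutation threshold, including runs on chromosomes 1, 2, 4, 5, 17, 20, 22 and X.

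The authors' deposited table called 8592 genes at an adjusted p under 0.05, 4073 higher and 4519 lower. Of these 8224 were also called here, all with the same sign, 1388 were called here only and 368 in the authors' deposited table only, 365 of which the filter had left out. Both rest on the same libraries. In the authors' deposited table of KEGG pathways 19 of 323 terms had an adjusted p under 0.05. It counted 866 changed genes with an annotation, against 9395 annotated genes in its background. The threshold behind these 866 is not known here, so the pathway counts need not be drawn from the 8592 genes. The authors' deposited table gave Cell adhesion molecules with 33 changed genes (16 higher, 17 lower) and ECM-receptor interaction with 25 (17 higher, 8 lower) the smallest adjusted p, 4.03e-05 for each. Protein digestion and absorption, a term that holds many collagens, had 23 changed genes (19 higher, 4 lower) in the authors' deposited table. PPAR signaling pathway (2 higher, 14 lower) and Steroid biosynthesis (2 higher, 6 lower) each had an adjusted p of 0.0332 there.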

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

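The edgeR test, TMM scaling, window-centring and the list tests without shifted windows or without APP were chosen only after the data were seen. The number of changed genes, 9612, stayed within 1.5 times under each alternative, from 8185 (adjusted p under 0.01) to 10320 (no low-count filter), with 8913 for DESeq2, 9680 for edgeR and 9042 to 9330 when each library was left out. The fold change of APP ranged from -7.05 (library size only) to -6.91 (upper quartile factors) over the scalings, and from 12 to 14 chromosomes passed. The number of called lists was 0 with an estimated correlation and 29 with fry (markers of other cell types apart), which asks only whether a list moves one way. Without the low-count filter the lists of APOE and lipoprotein receptors, adipocyte genes, inhibitors of adipogenesis and mitotic genes were called as well (13 in all). Called marker lists numbered 1 with library size only, 1 without the low-count filter, 1 with window-centring and 2 with fry, against 0; apart from fry, the cause was not tested. Directions were compared only where the main result or the alternative passed the threshold. Over all alternatives 3534 values of named genes kept their side of the threshold without a reversal, 10 kept direction only and 8 reversed. For lists 658 kept their side of the threshold without a reversal, 34 newly passed, 10 no longer passed and 0 reversed. Lists that passed in neither could still change direction, as oxidative phosphorylation did from upward to downward with library size only. The 8 reversals all came with window-centring, which measures a gene against its neighbours: GNAS -0.062, RPL3 -0.028, WDR1 0.091, RPL10 0.31, MSN 0.23, TERT -0.58, CCT5 -0.40 and KIAA1109 0.21. With it 8866 genes were called, 7423 of the 9612 among them and 264 of these 9612 called with the other sign. MT-CO1 and BNC1 lost their calls with library size only. The replicate numbers did not pair the libraries: same-numbered libraries deviated from their group means with correlations of 0.026, -0.014 and 0.021, and the replicate block gave 9827 changed genes. At this depth a count of 0 allows up to 3 reads in a library, so folds against it are lower bounds.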

Other observations

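The HOX, amino-acid and tubulin lists and the tests of residual APP reads, of scaling, of neighbouring windows and of other splits for lists and chromosomes were chosen only after the results were seen, as were the genes named in them. The p-values of these lists rest on the data that led to their choice and are descriptive only. Amino-acid synthesis and uptake genes fell in the knockout line: 23 of 29 were lower and 4 higher (median -0.76, camera adjusted p = 1.98e-06; adjusted p = 0.152 with an estimated correlation). PSAT1, an enzyme of serine synthesis, fell from 2186.6 ± 56.3 to 488.5 ± 115.6 (-2.19, SE 0.18), and SLC7A5, which imports large neutral amino acids, fell from 1294.9 ± 10.6 to 295.2 ± 59.1 (-2.15, SE 0.10). ASS1 (-1.88) of arginine synthesis fell with them, as did NUPR1 (-1.69), a stress regulator that was also placed in this list. Without genes of shifted windows the camera adjusted p was 7.88e-08.

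Tubulin genes fell as well, 10 of 14 lower and 1 higher (median -0.51, camera adjusted p = 0.00309; adjusted p = 0.109 with an estimated correlation). TUBB2A (-1.08), TUBB6 (-1.0), TUBB4B (-0.70) and TUBA1C (-0.65) fell; tubulin genes are close paralogues and may share reads, and the median stayed between -0.62 and -0.48 over the scalings, among them library size only, which gave 3632 higher genes in all. HOX genes, which mark body position, had 10 falls and 3 rises among 19. As a list they did not pass camera's threshold (adjusted p = 0.179, and 0.218 with an estimated correlation), except without genes of shifted windows (0.0406). With fry they passed (adjusted p = 1.37e-05). HOXD10 fell from 87.2 ± 13.3 to 8.53 ± 1.82 (-3.29) and HOXC8 from 141.2 ± 11.2 to 38.7 ± 2.93 (-1.85), and HOXB4 (0.79) and HOXB3 (0.64) rose.

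The regional shifts have a neighbour correlation of 0.732 between the medians of adjacent windows, against -0.222 to 0.217 in 10000 shuffled orders, which argues against changes of single genes or small clusters alone. A candidate explanation is a difference in chromosome copy number between the lines. It would move most genes of a segment at any expression level. Of the genes in the 33 segments 76.5% lay on their segment's side of the median, 81.9% in the higher expressed genes of each segment and 71.2% in the lower expressed ones. In 8 segments with 1423 genes 75% was reached in both groups of genes, while 2 segments lay under 65% over all their genes. Segments were picked for a shifted median in these same data, so a majority on that side follows from the choice. Whether noise lowers the share of lower expressed genes was not tested. Copy number and shared regulation of long domains cannot be told apart from these expression values, and neither an effect of APP loss on these regions nor another origin of the edited cells was tested.

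The residual APP reads, 278 over the APP_KO libraries or 0.807% of the WT level (exact interval 0.715% to 0.908%), may be transcripts of the edited alleles or reads from elsewhere. Reads crossing from WT into APP_KO libraries at that share would give AP001476.1 36.7 APP_KO reads, and it had 6. As this is 1 gene picked from many, such crossing is not excluded. For crossing the other way, CDH6 had 0 WT reads where 112.5 would be predicted and CDH13 2 where 44.8 would be. These genes argue only against crossing from APP_KO into WT libraries, which would not bring APP reads into APP_KO. A remnant of unedited cells would leave every abundant WT gene at that share or above. Only 1 gene, AP001476.1 at 0.132% (interval 0.0484% to 0.287%), lay clearly under it, fewer than the 3 set as the bound. That gene goes against such a remnant, but it is 1 gene picked from many. The bound was itself set after the results were seen. Unedited cells and transcripts of edited alleles are therefore not told apart here. The design text also calls the knockout conditional, and whether the edited cells are clonal is not given in the sources used here, so incomplete editing stays open as well.

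The share of reads on collagens could by itself have shifted the scale of all other genes. The median fold of COL1A1, COL1A2 and COL3A1 was 5.71 or more under every scaling tried, so the rise of collagens does not rest on the choice among these scalings. They moved the median of all genes only from -0.11 to 0.027 on the log2 scale, so a rise of this size could not have been undone by them. Higher calls made up 37.3% with library size only, 42.6% when the 10 most abundant genes were left out of each total and 47.5% with the authors' size factors. Leaving those genes out thus closed 51.7% of the gap, and 47.7% to 55.6% when each library was left out, on both sides of the bound of 50%; size factors of this kind also centre the median fold (-0.0082), so the part of a few abundant genes in this balance stays open. An untested biological alternative is that total messenger RNA per cell differs between the lines.

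Of the 10 ways to split the 6 libraries into 3 and 3, a share under 0.05 cannot be reached. With limma, 1 split, the real one, gave 9612 changed genes, and the highest of the others gave 0. For lists 2 splits, the real one included, gave at least the real number of 9, and the highest other gave 9. For chromosomes 6 splits, the real one included, gave at least the real number of 13, and the highest other gave 16. The other splits mix the groups unevenly, which moves much of the difference between WT and APP_KO into the spread within each new group. Few gene calls are then left whenever that difference is large, so their count of 0 says little about chance. They also keep part of that difference, and camera and the permutation of genes rank genes against each other whatever its size. The counts for lists and chromosomes therefore do not bear on chance. By library, the median of chromosome 5, picked for its shift between these libraries, relative to WT was 0.40 to 0.44 in APP_KO and -0.016 to 0.0056 in WT.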
